A study of Mus musculus with 27 samples.

How the data were processed

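The series holds bulk RNA sequencing of 27 mouse libraries in 9 groups of 3: bone marrow derived macrophages, embryonic fibroblasts, and cells labelled aortic endothelial, each at 0 h (unstimulated) and after 1 and 2 h with imidazole propionate (ImP) at 10 µg/mL. Per the labels, macrophage and fibroblast libraries were made with a directional kit and the libraries labelled aortic endothelial with a low-input kit, all sequenced on 1 instrument model, so the kit cannot be told apart from the cell type. The labels give no time-matched vehicle group, no animal or culture for each library, and no sequencing batch.

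The deposited values are estimated counts per gene symbol. Per the submitters' processing notes, the tools were cutadapt, FastQC, STAR, RSEM, R 4.3.2 and DESeq2 on the GRCm38 assembly; the notes give no versions for the other tools, no settings and no strand of counting, and since RSEM is the only counter named the values were taken as its expected counts. The expected counts were to be rounded before use, and all deposited values were already whole. The table holds 25192 gene symbols, and the per-group tables hold the same values cell by cell. Symbols were matched to GENCODE M21 for gene length and position, 98.2% in all (24506 by symbol and 224 by synonym, 462 not matched). No pair of libraries within a group held the same counts: over 27 pairs of replicates the lowest chi-squared per degree of freedom was 5.89. Pairs across groups were not compared in this way.

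Each cell type was fitted on its own with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM scaling, robust dispersions and the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over the genes tested (13251 in macrophages, 14066 in fibroblasts, 14779 in the libraries labelled aortic endothelial) and a threshold of 0.05. The comparisons were 1 h against 0 h, 2 h against 0 h, 2 h against 1 h, and any difference among the times. Differences of the ImP change between cell types were tested as interaction terms in 1 model of all 27 libraries (17038 genes). The biological coefficient of variation was 0.126, 0.126 and 0.326 in the order above. Total counts per library were 28.8 to 35.6, 30.6 to 36.5 and 19 to 61 M. Errors of log2 fold changes are edgeR standard errors, levels are CPM, TMM-scaled within a cell type for named genes, given as mean ± SD over 3 libraries, and detection floors of 3 counts cover counting error only.

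The groups, comparisons, gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. Genes named for 1 h or 2 h against 0 h are, among called genes with a mean of at least 1 CPM and all 3 ImP libraries above or below all 3 unstimulated ones, up to 10 in each direction by fold change; for 2 h against 1 h, and without the condition on overlap for differences between cell types, up to 5 in each direction. Predicted genes, clones and pseudogenes are counted and not named, and some other genes are not reported here. Where no gene was called, the 5 genes of each direction with the smallest p are named as not passing. From each gene list up to 4 members with the smallest p in that comparison are named, and Nisch is named in every cell type. Genes given by library (Nfkbia, Tnf, Il1b, Ifit1) and Id1 and Smad6 in the macrophage lists were chosen after their values were seen. Gene lists with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with a correlation estimated from these libraries and with fry; counts of members are given over all genes tested and adjusted over the list alone. The lists reported are the immediate early response, NF-kB and inflammatory cytokines, the interferon response, TGF-beta targets, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, extracellular matrix, mitosis, circadian clock, cholesterol synthesis, mTOR pathway components, glucocorticoid targets and p53 targets, with markers of macrophages, fibroblasts, endothelial cells and smooth muscle for the levels of cell type genes.

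The alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, library totals alone, no low-count filter, a filter at a mean of 1 CPM, a fit of the compared groups alone, runs of library codes as a block, an absolute log2 fold change of at least 1, and leaving out each library in turn. Chosen after the values were seen were a fit without the third 1 h and the third 2 h macrophage library, a fit with each library's trend on gene length removed, and that fit without the first fibroblast 1 h library as well. The tests were also run on simulated data, drawn after the main fits from their levels and dispersions. Counts were drawn for the real genes with 200 genes changed. These had a mean of at least 1 CPM and were moved alike in all 3 libraries of the 1 h group. EdgeR found 64% of 1.5-fold and 86% of 2-fold changes in macrophages at 1 h (13051 genes) and 67% and 83% in fibroblasts (13807 genes). In the libraries labelled aortic endothelial it found 16% and 54% (14320 genes). Of the edgeR calls 8.54%, 4.46% and 4.11% were false, and of the DESeq2 calls 16.8%, 15.8% and 20.6%. For differences between cell types at 1 h, 2-fold differences were found for 58% of genes between macrophages and fibroblasts (16670 genes), 54% between the libraries labelled aortic endothelial and macrophages (16649 genes) and 57% between those libraries and fibroblasts (16647 genes). No library was left out of the comparisons as labelled.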

Results

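Gene expression was measured by bulk RNA sequencing in 27 mouse libraries from 3 cultured cell types: bone marrow derived macrophages, embryonic fibroblasts, and cells labelled aortic endothelial. Each cell type was left unstimulated (0 h) or was given imidazole propionate (ImP), a metabolite that gut bacteria make from histidine, at 10 µg/mL for 1 or 2 h. Each of the 9 groups held 3 libraries. The series asks which transcriptional programmes ImP raises in each cell type, in the setting of atherosclerosis. The labels do not say that replicates came from separate cultures or animals. The p-values therefore measure only the spread between these samples, which may be technical. The labels give no vehicle group at 1 or 2 h, so a change with ImP and a change with time in culture share the same comparison.

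The macrophage libraries carried the transcripts of their cell type. All 12 macrophage markers measured had a mean of at least 10 CPM over 9 libraries, led by the lysozyme gene Lyz2 (15000 CPM) and including the scavenger receptor Cd68 (2090 CPM). In the fibroblast libraries 7 of 11 fibroblast markers reached 10 CPM, led by the collagen genes Col1a1 (2370 CPM) and Col1a2 (1730 CPM). Col3a1 (2.23 CPM) and Thy1 (0.682 CPM) did not, and 1 of 14 endothelial markers did, the VEGF receptor Flt1 (102 CPM). The libraries labelled aortic endothelial lacked most endothelial transcripts. Of 14 endothelial markers only Eng, a co-receptor for TGF-beta family ligands, reached 10 CPM (105 CPM). Another 8 lay under 1 CPM, among them the junctional cadherin Cdh5 (0.569 CPM) and the VEGF receptor Kdr (0.212 CPM). The adhesion molecule Pecam1 stood at 1.37 CPM. In the same libraries 9 of 11 fibroblast markers and 5 of 8 smooth muscle markers exceeded 10 CPM. These included the surface glycoprotein Thy1 (451 CPM), the PDGF receptor Pdgfra (336 CPM) and smooth muscle actin Acta2 (798 CPM). Results on these libraries therefore refer to their label and not to a checked cell identity.

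**Figure D1:**
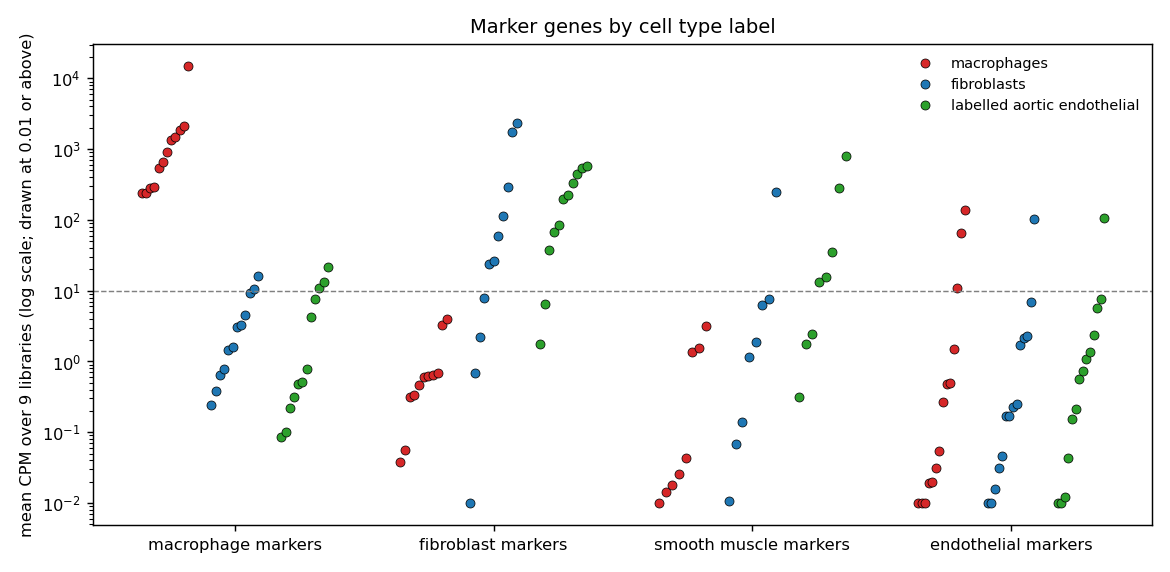
Mean CPM over the 9 libraries of each cell type label, 1 point per marker gene, on a log scale with values under 0.01 drawn at 0.01 and a dashed line at 10 CPM. In the libraries labelled aortic endothelial (green), 1 of 14 endothelial markers lies above the line, against 9 of 11 fibroblast markers.

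The third macrophage library at 1 h and the third at 2 h stood apart from the other libraries of their groups. Nfkbia, which encodes an inhibitor of NF-kB and is itself an NF-kB target, was at 39.8, 36.2 and 36.5 CPM at 0 h. It was at 225, 216 and 40.8 CPM at 1 h, and at 44.9, 36.6 and 233 CPM at 2 h. The inflammatory cytokine gene Tnf had the same layout, with 228, 222 and 18.2 CPM at 1 h and 14.3, 18.4 and 267 CPM at 2 h. The macrophage comparisons are therefore given as labelled and again with the third library of each ImP group left out. That second fit was chosen after the values were seen. Because the libraries were chosen on the outcome, its p-values are smaller than those of a test set in advance.

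**Figure D2:**
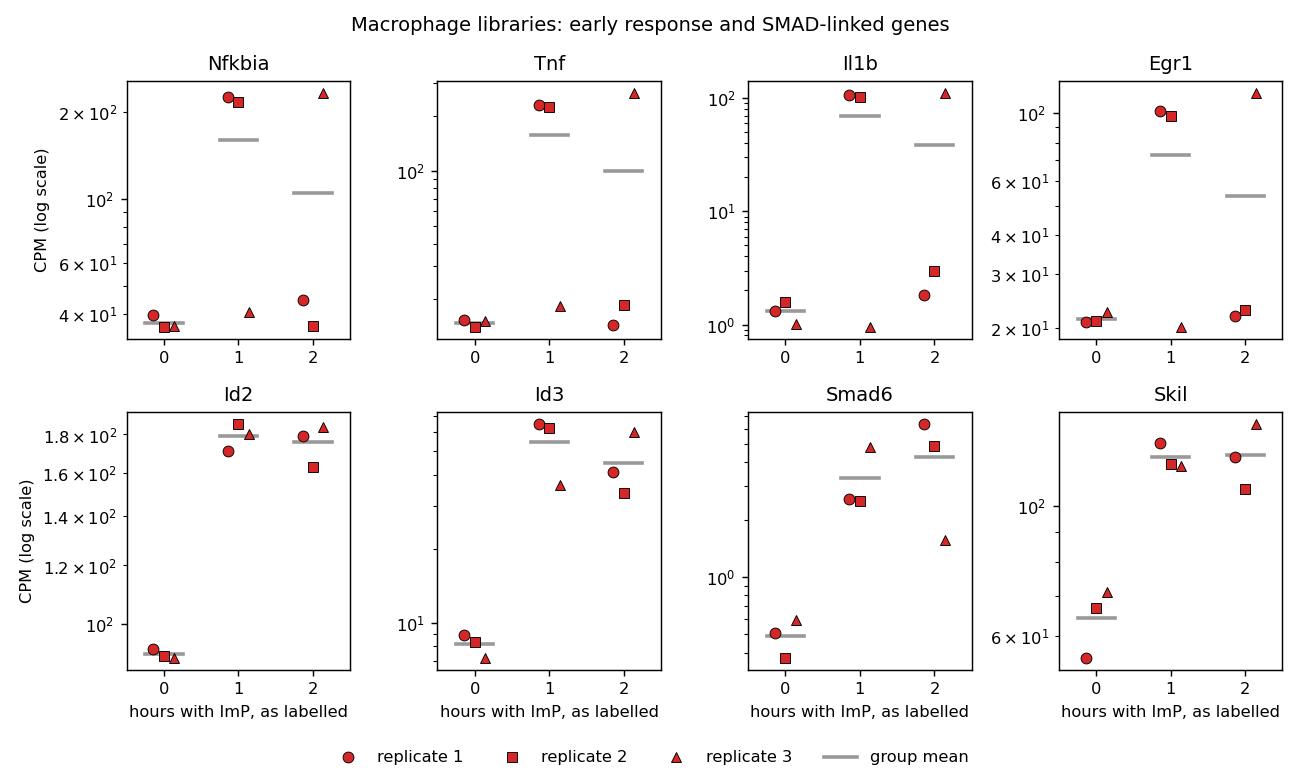
CPM on a log scale (axes differ) of 8 genes in the 9 macrophage libraries by hours with ImP as labelled; symbols are the 3 replicates and grey bars the group means. For Nfkbia, Tnf, Il1b and Egr1 the third library at 1 h lies near the 0 h libraries and the third library at 2 h near the other 1 h libraries, while all 6 ImP libraries lie above 0 h for Id2. For Id3 and Smad6 all 6 also lie above 0 h, but the third libraries lie nearer the other ImP group.

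After 1 h with ImP, macrophages had higher transcripts of 3 genes, each above 0 h in 3 of 3 libraries. Id2, a helix-loop-helix inhibitor induced by BMP and TGF-beta signalling, rose by 0.97 on the log2 scale (SE 0.061, edgeR Benjamini-Hochberg adjusted p = 2.55e-06). Its level went from 91.2 ± 1.3 to 179 ± 8 CPM (SD, 3 libraries each). Skil, a SMAD-binding repressor that TGF-beta induces, rose by 0.91 (SE 0.103, edgeR adjusted p = 0.007), from 64.4 ± 8.5 to 121 ± 5.8 CPM. Bhlhe40, a transcription factor of the circadian clock and of macrophage activation, rose by 0.49 (SE 0.063, edgeR adjusted p = 0.007), from 34.9 ± 0.38 to 49.2 ± 0.84 CPM. Among 13251 genes tested, edgeR called 3 higher and 0 lower, and 693 had an unadjusted p under 0.05. DESeq2 called 12 higher and 1 lower, and limma-voom 5 higher. On the GRCm38 assembly Id2 lies on chromosome 12 at 25093799 to 25097140, Skil on chromosome 3 at 31095058 to 31122577, and Bhlhe40 on chromosome 6 at 108660629 to 108666925. Bhlhe40 overlaps 0610040F04Rik on the opposite strand. The strand of counting is not stated, so its value is uncertain to that extent, as are those of other genes named below as overlapping.

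The TGF-beta targets rose as a group at 1 h in macrophages. All 15 measured members had a positive log2 fold change (median 0.85), and the list passed camera (adjusted p = 1.75e-40) and held with an estimated correlation (adjusted p = 0.000231). Over all genes 2 members passed, Id2 and Skil, and 8 passed when adjusted over the list alone. These included Id3 (2.73, SE 0.308), Smad6 (2.74, SE 0.533), Id1 (1.73, SE 0.349) and Smad7 (0.85, SE 0.172). For Id3 the edgeR adjusted p was 0.000294 over the list and 0.149 over all genes. Id1 and Id3 belong to the family of Id2, and Smad6 and Smad7 are inhibitory SMADs that feed back on BMP and TGF-beta receptors. Other lists that passed camera in macrophages at 1 h were lost with an estimated correlation. Of 29 immediate early genes 0 passed over all genes in edgeR and 1 over the list alone, Fosb (1.35, SE 0.298) (camera adjusted p = 2.16e-17, adjusted p = 0.158 with an estimated correlation). Of 31 NF-kB and inflammatory cytokine genes 0 passed in edgeR (camera adjusted p = 4.44e-16, adjusted p = 0.307 with an estimated correlation). The third library of each ImP group lay apart from its group in both lists. It also did so for Id3 and Smad6 among the TGF-beta targets, though above 0 h. Id3 was at 64.7, 62 and 36.5 CPM at 1 h and 41.1, 33.7 and 60.1 CPM at 2 h. Smad6 was at 2.57, 2.51 and 4.82 CPM, then at 6.35, 4.88 and 1.57 CPM. Their sizes at each time therefore depend on the labels of these libraries. Id2 did not show this, at 171, 186 and 180 CPM, then at 179, 163 and 184 CPM. The 77 cytosolic ribosomal protein genes had a median of -0.15 with 0 past the threshold in edgeR (camera adjusted p = 1.4e-32, adjusted p = 0.225 with an estimated correlation). Deviations from the macrophage mean had rank correlations with gene length of -0.35, -0.13 and 0.097 at 0 h and 0.066, -0.13 and 0.16 at 1 h (10741 genes).

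With the third library of each ImP group left out, 111 macrophage genes were higher and 14 lower at 1 h among 13465 tested. The largest rises were those of inflammatory mediators, each above 0 h in both remaining libraries. They included the cytokine Il1b (6.29, SE 0.167, edgeR adjusted p = 1.28e-09), the chemokines Cxcl2 (6.11, SE 0.184) and Cxcl1 (5.58, SE 0.428), and the cytokine signalling inhibitor Socs3 (5.53, SE 0.146). The TNF family ligand Tnfsf9 (4.83), the NF-kB cofactor Nfkbiz (4.50, SE 0.099), Tnf (3.92, SE 0.095), the prostaglandin synthase Ptgs2 (3.89), Il1a (3.57) and the itaconate enzyme Acod1 (3.54) followed. Il1b, Il1a and Tnfsf9 each overlap a gene on the opposite strand. Of 32 NF-kB and inflammatory cytokine genes 20 rose and 0 fell (adjusted p = 5.15e-05 with an estimated correlation). Of 29 immediate early genes 14 rose, with Egr1 (2.20, SE 0.076), the stress response gene Ier3 (2.29, SE 0.112) and the mRNA decay factor Zfp36 (1.32, SE 0.065) at the smallest p. That list held with an estimated correlation (adjusted p = 0.00669). Of 15 TGF-beta targets 5 rose (adjusted p = 0.00669 with an estimated correlation), with Id3 at 2.95 (SE 0.11, edgeR adjusted p = 1.28e-09) and Smad6 at 2.36 (SE 0.295). Among the falls were the prostaglandin receptor gene Ptger1 (-1.17, SE 0.195), mitochondrially encoded mt-Nd3 (-0.51) and mt-Co3 (-0.40), and ribosomal protein genes led by Rpl35 (-0.43), with Rpl39, Rps28, Rps27 and Rps24. Ifi27l2a and Npy also fell. The libraries left out did not all share these falls. The gene mt-Nd3 was at 250 to 271 CPM at 0 h and at 168 and 203 CPM in the kept 1 h libraries. It was at 263 and 240 CPM in the third 1 h and 2 h libraries. Rpl35 was at 62 to 65.4, at 46.2 and 49.8, and at 57.8 and 65.8 CPM in that order. Ptger1 was at 10.5 to 12 CPM at 0 h and at 5.16 and 9.89 CPM in these libraries. Rps28 was at 157 and 148 CPM in them, against 168 to 179 CPM at 0 h. Leaving out 1 library alone gave 7 genes without the third 1 h library and 7 without the third 2 h library.

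After 2 h with ImP, the same 3 genes were again higher in macrophages, together with Filip1l. Id2 rose by 0.95 on the log2 scale (SE 0.061, edgeR adjusted p = 3.58e-06), to 176 ± 11 CPM. Skil rose by 0.92 (SE 0.103, edgeR adjusted p = 0.00499), to 122 ± 15 CPM, and Bhlhe40 by 0.51 (SE 0.063, edgeR adjusted p = 0.00499), to 49.8 ± 0.33 CPM. Filip1l, which encodes a filamin A interacting protein, rose by 0.79 (SE 0.121, edgeR adjusted p = 0.042), from 11.7 ± 1.6 to 20.3 ± 2.6 CPM. It lies on chromosome 16 at 57353093 to 57573126 and overlaps Cmss1 on the opposite strand. In all edgeR called 4 genes higher and 0 lower, and 815 had an unadjusted p under 0.05. DESeq2 called 14 higher and 1 lower, and limma-voom 4 higher. The TGF-beta targets again had 15 of 15 positive values (median 0.75, camera adjusted p = 1.48e-36, adjusted p = 0.000313 with an estimated correlation). Over the list alone 7 were higher, including Smad6 (3.12, SE 0.534, from 0.491 ± 0.11 to 4.27 ± 2.4 CPM) and Id3 (2.46, SE 0.307, from 8.15 ± 0.89 to 45 ± 14 CPM). The nuclear-encoded oxidative phosphorylation genes had a median of -0.11 with 5 of 26 lower over the list alone, such as Cox7c (-0.27, SE 0.066) and Ndufa2 (-0.35, SE 0.091). That list was lost with an estimated correlation (camera adjusted p = 4.79e-09, adjusted p = 0.194 with an estimated correlation). Deviations from the macrophage mean had rank correlations with gene length of -0.35, -0.13 and 0.097 at 0 h and 0.073, 0.23 and -0.00089 at 2 h. The list was not tested with this trend removed.

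The macrophage calls differed in how much they rested on single libraries. Id2 passed in 19 of 19 alternatives at both times, which leave out the minimum absolute log2 fold change of 1 that its values of 0.97 and 0.95 do not reach. The Skil call ended at 1 h without the second 0 h library (adjusted p = 0.0862, in a range from 1.57e-13). At 2 h it ended without the first 2 h library (adjusted p up to 0.0926, from 6.72e-14). The Bhlhe40 call ended at 1 h without the third 0 h library (adjusted p up to 0.063, from 6.37e-09). At 2 h it ended without the first or the second 2 h library (adjusted p up to 0.0528, from 7.29e-10). With 1 library left out, Filip1l stayed past the threshold only when it was the second 0 h library, with an adjusted p from 1.01e-05 to 0.249 over all alternatives. The count at 2 h was 1 without the first and 2 without the second 2 h library. With the third library of each ImP group left out, 15 genes were higher and 1 lower at 2 h. Smad6 (3.52, SE 0.289, edgeR adjusted p = 7.64e-05), Id3 (2.20, SE 0.11, edgeR adjusted p = 5.15e-07), Id2 (0.91) and Skil (0.83) rose most. The poly(A) polymerase gene Tent5c (0.64, SE 0.093), Engase, Pwwp2b, Kif21b, Enc1 and Bhlhe40 also rose. In that fit 4 of 15 TGF-beta targets rose (adjusted p = 0.0145 with an estimated correlation).

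Between 1 and 2 h no macrophage gene passed as labelled. EdgeR called 0, with 218 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 1 each. The smallest p belonged to Ssx2ip (0.36, SE 0.112), the serine racemase gene Srr (0.30, SE 0.094), Vps4a (0.21), the planar polarity gene Fuz (-0.56, SE 0.14), Ppif (-0.46), Rab3a (-0.83), Snx25 (-0.29) and Fbxl5 (-0.22). All were at an edgeR adjusted p of 1. Ccdc88c (1.85, SE 0.589) rested on 4, 4 and 5 counts at 1 h, and Tmc3 had 0 counts in every 1 h library against 17, 18 and 4 at 2 h. With the third library of each ImP group left out, 7 genes were higher and 82 lower at 2 h than at 1 h. The largest falls were those of Cxcl2 at -5.54 (SE 0.209, edgeR adjusted p = 2.35e-07), Il1b at -5.43 (SE 0.186), Cxcl1 at -4.76, Socs3 at -4.75 and Tnfsf9 at -4.35. Of 32 NF-kB and inflammatory cytokine genes 18 fell (adjusted p = 5.8e-05 with an estimated correlation), as did 12 of 29 immediate early genes (adjusted p = 0.0146 with an estimated correlation). The potassium channel gene Kcnj2 (0.59, SE 0.094), Mef2a, Itgav and Top1 rose.

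Tested over both times together, 3 macrophage genes changed in edgeR, with 563 at an unadjusted p under 0.05. DESeq2 called 16 and limma-voom 5, and edgeR called 130 with the third library of each ImP group left out. The 1 h and 2 h changes were set against the same unstimulated libraries, so part of their likeness is shared chance. Across 13251 genes, which are not independent replicates, the log2 fold changes had a correlation of 0.625 against 0.506 in 20 simulations of unchanged groups. Their covariance was 0.0931 against 0.0648. The correlation was 0.372 against 0.391 and the covariance 0.084 against 0.0626 with the third library of each ImP group left out, so the correlation then did not exceed the mean of the simulations. In that fit 6 genes were called at both times, among them Bhlhe40, Id2, Id3, Skil and Smad6, against at most 2 in the simulations. As labelled, Bhlhe40, Id2 and Skil were called at both times, 3 genes against at most 2 in the simulations and 0.00091 for independent lists of these sizes. With 3 unstimulated libraries the controls could not be split, so part of this likeness may come from sharing them.

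**Figure D3:**
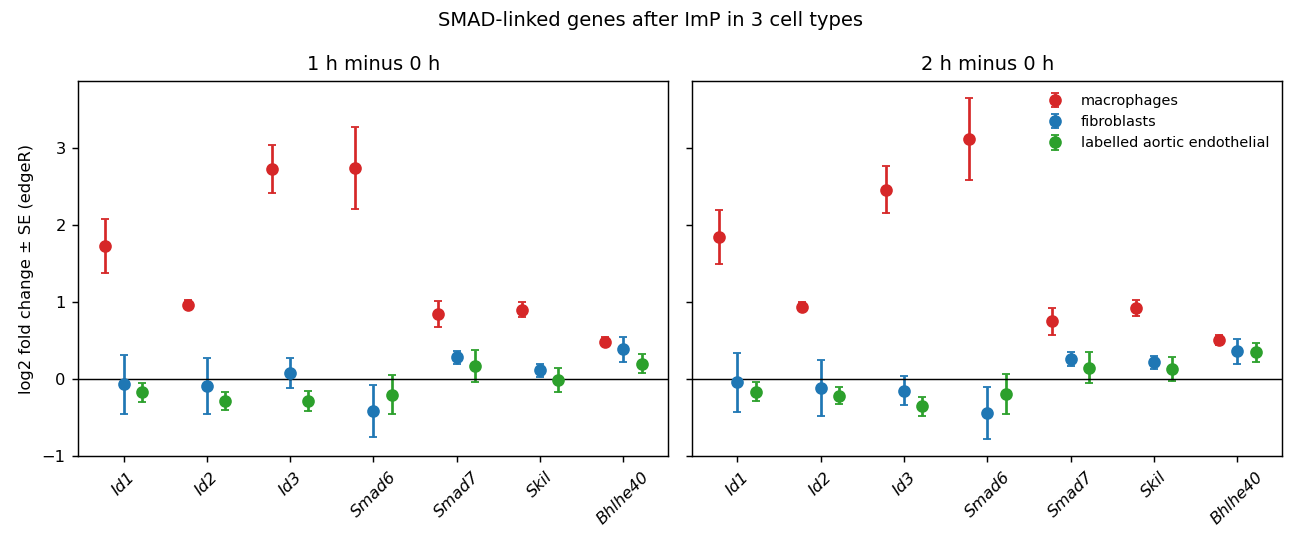
Log2 fold changes with standard errors (edgeR, 3 libraries per group) of 7 genes of SMAD signalling or of the macrophage calls, at 1 h and 2 h against 0 h, in macrophages (red), fibroblasts (blue) and libraries labelled aortic endothelial (green). In macrophages Id3 is at 2.73 at 1 h and Smad6 at 3.12 at 2 h, and the values of the other two cell types for these genes lie near or below 0.

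In fibroblasts after 1 h, no gene passed the threshold among 14066 tested. EdgeR called 0, with 826 at an unadjusted p under 0.05, DESeq2 called 9 higher and 1 lower, and limma-voom 0. On the higher side, the smallest p belonged to early response genes. They were the orphan nuclear receptor Nr4a1 (0.61, SE 0.114, from 14.5 ± 1.5 to 22.1 ± 0.87 CPM), Nfkbia (0.65, SE 0.12, from 119 ± 11 to 186 ± 18 CPM), the NF-kB inhibitor Tnfaip3 (0.63, SE 0.12), the interferon regulatory factor Irf1 (0.46) and Phlda1 (0.34). Each was above 0 h in 3 of 3 libraries, at an edgeR adjusted p of 0.566 to 0.57. On the other side were Farp2 (-0.62, SE 0.118, edgeR adjusted p = 0.566) and, at 0.846, Spen (-0.45), the kinetochore gene Cenpf (-0.33), the histone methyltransferase Kmt2d (-0.35) and Tenm3 (-0.31). Over the alternatives Spen shrank to as little as -0.274, Cenpf to -0.122, Kmt2d to -0.191 and Tenm3 to -0.192, while Farp2 stayed at -0.549 or lower. Of 29 immediate early genes 28 had a positive value, 0 passed over all genes in edgeR and 13 were higher when adjusted over the list alone. Among these were Fosb (1.88, SE 0.351), Egr3 (0.93, SE 0.212) and Csrnp1 (0.36, SE 0.084), and the list was lost with an estimated correlation (camera adjusted p = 4.5e-26, adjusted p = 0.133 with an estimated correlation). Deviations from the fibroblast mean had rank correlations with gene length of -0.016, -0.052 and 0.22 at 0 h and 0.037, -0.4 and -0.47 at 1 h. With this trend removed edgeR had 559 genes at an unadjusted p under 0.05, and the lists were not tested in that fit. Of 31 NF-kB genes 3 were higher over the list alone, Nfkbia, Tnfaip3 and Irf1 (camera adjusted p = 4.97e-14, adjusted p = 0.295 with an estimated correlation). The interferon response had 24 of 24 positive values with 0 past the threshold in edgeR (camera adjusted p = 8.34e-06, adjusted p = 0.487 with an estimated correlation). Here the first 1 h library stood apart, with Ifit1 at 22.3 CPM against 11.4 and 9.75 CPM in the others and 9.7 to 11.1 CPM at 0 h. Leaving out the third 2 h library gave 1 call. With runs of library codes as a block edgeR called 1 gene, Nfkbia.

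**Figure D4:**
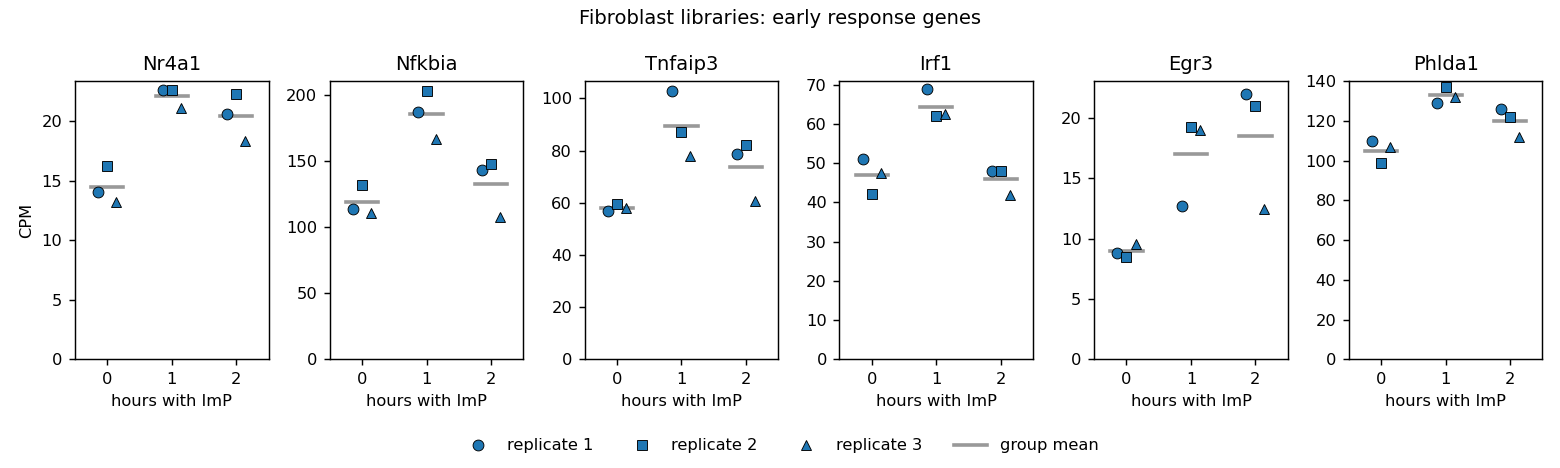
CPM of 6 early response genes in the 9 fibroblast libraries by hours with ImP; symbols are the 3 replicates and grey bars the group means. Nr4a1 has a mean of 14.5 CPM at 0 h and 22.1 CPM at 1 h, and Nfkbia 119 and 186 CPM, none of which passed the threshold over all genes.

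After 2 h no fibroblast gene passed either. EdgeR called 0, with 342 at an unadjusted p under 0.05, DESeq2 called 5 higher, and limma-voom 0. The smallest p belonged to Zfp469 (0.42, SE 0.077, from 107 ± 10 to 143 ± 3.9 CPM), the zinc finger gene Hivep2 (0.62, SE 0.121), the early growth response gene Egr3 (1.04, SE 0.212, from 8.96 ± 0.56 to 18.5 ± 5.2 CPM) and the scaffold protein gene Ahnak (0.40). On the other side were Washc3 (-0.38, SE 0.11), Pgpep1 (-0.26) and the heparin-binding growth factor Ptn (-1.18, SE 0.37). All were at an edgeR adjusted p of 1. Others were at few counts. Cd247 had 0 counts in every 0 h library and 16, 30 and 2 at 2 h. Tbx3os1 had 17, 19 and 8 counts against 4, 1 and 2, and Olfr373 had 13, 10 and 6 against 0, 1 and 2. Of 29 immediate early genes 5 were higher over the list alone, among them Egr3, Nr4a1 (0.49, SE 0.113), Dusp5 and Fosl1 (camera adjusted p = 2.86e-14, adjusted p = 0.144 with an estimated correlation).

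Between 1 and 2 h in fibroblasts, edgeR called 0 genes, with 1709 at an unadjusted p under 0.05. DESeq2 called 242 higher and 66 lower, and limma-voom 0. The smallest p on the higher side belonged to Hivep3 (0.62, SE 0.095), Zfp469 (0.47, SE 0.077), the kinase gene Mast4 (0.38), Zmiz1 (0.41) and the ubiquitin ligase Birc6 (0.41). On the lower side were Irf1 (-0.50, SE 0.091), the RNA polymerase subunit Polr2e (-0.39, SE 0.083), Churc1, Fopnl and Washc3, all at an edgeR adjusted p of 0.142 to 0.152. Over the alternatives Hivep3 shrank to as little as 0.321, Mast4 to 0.07, Zmiz1 to 0.276 and Birc6 to 0.161, while Zfp469 stayed at 0.45 or higher. The cytosolic ribosomal protein genes had a median of -0.245 with 0 of 77 past the threshold over all genes in edgeR. Over the list alone 62 were lower, such as Rpl22 (-0.32, SE 0.073) and Rps18 (-0.34, SE 0.083) (camera adjusted p = 8.78e-38, adjusted p = 0.703 with an estimated correlation). Levels varied with gene length between these libraries. Across 11025 genes, deviations from the fibroblast mean had a rank correlation with length of -0.40 and -0.47 in the second and the third 1 h library, and of 0.26, 0.34 and 0.25 in the 2 h libraries. The extracellular matrix list had 4 members higher over the list alone, Fbn1 (0.38, SE 0.069), Col4a1, Col5a1 and Fn1 (camera adjusted p = 1.16e-05, adjusted p = 0.417 with an estimated correlation). Without the first 1 h library, whose length correlation was 0.037, edgeR called 222 genes higher and 143 lower. Of the lower genes 50 encoded ribosomal proteins, and with the length trend also removed edgeR called 1 gene. Over both times together edgeR called 0 fibroblast genes, with 1048 at an unadjusted p under 0.05, DESeq2 126 and limma-voom 0. Without the first 1 h library it called 30.

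In the libraries labelled aortic endothelial, edgeR called 0 of 14779 genes at 1 h, with 733 at an unadjusted p under 0.05. DESeq2 called 1 lower and limma-voom 0. The smallest p belonged to the palmitoyltransferase Zdhhc21 (0.82, SE 0.17), Plekhb2 (0.53, SE 0.12), Pskh1 (0.99) and the receptor Ror1 (1.05). On the other side were Ctla2a (-0.50, SE 0.141), Prl2c2 (-0.44), the cytokine gene Il18 (-1.80, SE 0.536) and the ciliary gene Cep290 (-0.83). All were at an edgeR adjusted p of 0.826. Serpina3c had 0 counts in every 0 h library and 28, 16 and 30 at 1 h. Tcte3 had 39, 33 and 32 counts at 0 h, 0 in every 1 h library and 12, 18 and 36 at 2 h. Serpina3c belongs to a family of close copies and Tcte3 overlaps Gm3448 on the same strand, so both are uncertain. At 2 h edgeR again called 0, with 1361 at an unadjusted p under 0.05, DESeq2 15 higher and 7 lower, and limma-voom 0. The leading genes were Angptl4, an inhibitor of lipoprotein lipase (0.70, SE 0.124, from 166 ± 6 to 271 ± 46 CPM), the glycoprotein hormone Stc1 (1.58, SE 0.289, from 8.84 ± 1.9 to 26.4 ± 11 CPM) and Nptx1 (1.24, SE 0.215), with Myo1e and Ptpn21. On the lower side were Serpinb9b (-0.58, SE 0.124), the matrix proteoglycan Ogn (-0.80, SE 0.18), Eno3 (-0.59), Gstm5 (-0.53) and Rnd1 (-0.68). All were at an edgeR adjusted p of 0.539, and Stc1 and Ogn each overlap a gene on the opposite strand. Leaving out the third 0 h library gave 1 call at 1 h and 1 at 2 h.

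Among gene lists in the libraries labelled aortic endothelial, 6 of 36 passed camera at 1 h and 6 at 2 h, and 0 did with an estimated correlation. The 1 h number was 3 without the first 1 h and 2 without the third 0 h library so labelled. At 2 h the ribosomal protein genes had a median of -0.38 with 0 of 77 past the threshold in edgeR (camera adjusted p = 2.59e-29, adjusted p = 0.694 with an estimated correlation). The third 0 h library stood apart, with 5.06% of its counts in ribosomal protein genes against 3.82% and 3.86% in the others at 0 h. Deviations from the mean of these libraries had rank correlations with gene length of -0.11, -0.012 and -0.30 at 0 h and 0.37, 0.098 and 0.055 at 2 h (11558 genes). The immediate early genes had a median of 0.24 (adjusted p = 0.694 with an estimated correlation). The circadian clock genes had a median of 0.30, with Cry1 at 1.00 (SE 0.323) (adjusted p = 0.694 with an estimated correlation). The mitosis genes had a median of -0.21, with Aurka at -0.42 (SE 0.162) (adjusted p = 0.723 with an estimated correlation). The cholesterol synthesis list had a median of -0.21 and 1 of 25 members lower over the list alone, Pmvk (-0.81, SE 0.199) (camera adjusted p = 0.0205, adjusted p = 0.828 with an estimated correlation). Between 1 and 2 h edgeR called 0, with 293 at an unadjusted p under 0.05, DESeq2 4 higher and 2 lower, and limma-voom 0. The smallest p belonged to Snap25 (1.25, SE 0.265), Angptl4 (0.57, SE 0.123), Dnm3os (0.74), Stc1 (1.17, SE 0.286), Ogn (-0.87, SE 0.18), Ms4a4d (-1.48), Plac9a (-0.90) and Adamtsl3 (-1.04), at an edgeR adjusted p of 1. Over both times together edgeR called 0, with 725 at an unadjusted p under 0.05, DESeq2 17 and limma-voom 0. At 1 h, simulated 2-fold changes were found for 54% of genes and 1.5-fold changes for 16% (14320 genes), against 86% and 64% in macrophages (13051 genes). The simulated changes moved all 3 libraries of the 1 h group alike. The macrophage shares therefore do not cover genes that the third 1 h library lacked, such as Tnf (228, 222 and 18.2 CPM at 1 h).

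Whether the response differed between cell types was tested in 1 model of all 27 libraries and 17038 genes. Id3 rose more in macrophages than in fibroblasts, by 2.64 on the log2 scale at 1 h (SE 0.304, edgeR adjusted p = 0.000115) and 2.58 at 2 h (SE 0.304, edgeR adjusted p = 0.000177). Smad6 did so at 2 h (3.53, SE 0.602, edgeR adjusted p = 0.0351). For both genes the third macrophage library of each ImP group lay apart from its group, so these sizes depend on the labels. In fibroblasts Id3 was at 72.9 ± 8.3, 76.9 ± 22 and 66 ± 11 CPM at 0, 1 and 2 h, so the cell type with the larger response began from the lower level. Of 15 TGF-beta targets, 9 had a positive value in fibroblasts at 1 h (median 0.09, camera adjusted p = 0.0247, adjusted p = 0.295 with an estimated correlation). In the libraries labelled aortic endothelial 6 of 15 did (median -0.007, and 0.035 with library totals, camera adjusted p = 0.546). The difference between cell types was tested for single genes and not for the list. In all edgeR called 1 gene higher at 1 h (616 at an unadjusted p under 0.05, DESeq2 5, limma-voom 1) and 2 at 2 h (372, DESeq2 4, limma-voom 1). With the third library of each macrophage ImP group left out, 26 were higher and 1 lower at 1 h, led by Cxcl2 (5.63, SE 1.01), Socs3 (5.50, SE 0.339, edgeR adjusted p = 6.6e-10), Tnfsf9, Cxcl1 and Nfkbiz.

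The calls between macrophages and fibroblasts rested in part on single libraries. Id3 was lost when only these cell types entered the fit (adjusted p = 0.0531 at 1 h and 0.069 at 2 h, in ranges from 4.98e-14 and 2.04e-13). The 1 h count became 2 without the first macrophage 0 h or the third macrophage 2 h library. It became 3 without the first fibroblast 0 h or the third fibroblast 1 h library. The Smad6 call at 2 h ended without any single macrophage 0 h library, the first or second macrophage 2 h library, any fibroblast 0 h or 2 h library or the second fibroblast 1 h library. Its adjusted p ran up to 1, from 1.39e-05, and 1 gene was left except without the first macrophage 0 h library.

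Against macrophages, the libraries labelled aortic endothelial differed at 1 h in Id3 (-3.04, SE 0.304, edgeR adjusted p = 7.79e-06), which was at 831 ± 140 CPM at 0 h and 687 ± 45 CPM at 1 h there. They also differed in Tbkbp1, an adaptor of the kinase TBK1 (-1.84, SE 0.318, edgeR adjusted p = 0.0423). At 2 h they differed in Id3 (-2.83, SE 0.303, edgeR adjusted p = 3.07e-05) and Smad6 (-3.31, SE 0.581, edgeR adjusted p = 0.0241). Further differences were those of the transporter gene Slc49a4 (-1.31, SE 0.212, edgeR adjusted p = 0.017) and the RNA sensor Tlr7 (3.35, SE 0.566, edgeR adjusted p = 0.0204). Tlr7 was near the detection floor in the libraries labelled aortic endothelial, with 4, 1 and 4 counts at 0 h and 22, 58 and 26 at 2 h. In total edgeR called 0 higher and 2 lower at 1 h (1138 at an unadjusted p under 0.05, DESeq2 47, limma-voom 1). At 2 h it called 3 higher and 6 lower (1337, DESeq2 106, limma-voom 1). With the third library of each macrophage ImP group left out, 2 were higher and 36 lower at 1 h. These included Cxcl2 (-7.70), Mir155hg (-6.41), Tnf (-6.40), Tnfsf9 (-5.26, SE 0.396) and the transcription factor Adnp (1.60, SE 0.305). The sizes for Cxcl2 and Tnf are uncertain, since counts in the libraries labelled aortic endothelial were near 0. Tnf had 3, 1 and 22 counts at 0 h and 5, 0 and 0 at 1 h there, and Cxcl2 had 55, 0 and 0 at 0 h and 9, 7 and 0 at 1 h. The size for Mir155hg is uncertain too, since macrophages had 0.0632, 0.0576 and 0 CPM at 0 h. At 2 h 2 were higher and 5 lower.

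These counts rested on single libraries. Without the first 0 h library labelled aortic endothelial the 1 h count was 62 and the 2 h count 148. Without the first 1 h library so labelled they were 49 and 16. The 1 h count was 6 without the third 2 h library so labelled or the third macrophage 2 h library. It was 5 without the third 0 h library and 4 without the second 1 h library so labelled. It was 1 without any 1 h macrophage library, the first or second 2 h or the second or the third 0 h macrophage library. The Tbkbp1 call ended without each of these macrophage libraries and without the second 0 h or the second or the third 1 h library labelled aortic endothelial (adjusted p up to 0.378, from 9.31e-05). The 2 h count was 17, 19 and 20 without the first, the second and the third 2 h library labelled aortic endothelial. It was 14 without the second 0 h and 21 without the third 1 h library so labelled. It was 4 without the third macrophage 0 h library and 1 without the second 0 h or the first or second 2 h macrophage library.

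Leaving out the second 0 h or the first or second 2 h macrophage library also ended the calls at 2 h of Slc49a4 (adjusted p up to 0.0689, from 1.84e-05) and Tlr7 (up to 0.285, from 2.93e-05). The same held for Smad6 (up to 0.263, from 2.93e-05), whose call ended without the first or the third macrophage 0 h library too. Id3 passed in 28 of 28 alternatives at both times.

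Between the libraries labelled aortic endothelial and fibroblasts, edgeR called 0 genes at 1 h (1873 at an unadjusted p under 0.05, DESeq2 81, limma-voom 0) and 0 at 2 h (1351, DESeq2 63, limma-voom 0). The smallest p at 1 h belonged to Zdhhc21 (0.88, SE 0.167), Gramd1b (1.34), Zfp687 (1.37), Als2cl (4.26), Tbkbp1 (-1.61, SE 0.327), Raet1d (-1.39), Coq8a (-2.19), Trem2 (-2.18), Smim24 and Tnfsf13os. They were at an edgeR adjusted p of 0.102 to 0.194. Some of these sizes are uncertain at levels near 0. Als2cl was at 0.134, 0 and 0 CPM at 0 h and 0.753, 0 and 3.1 CPM at 1 h in the libraries labelled aortic endothelial, and Coq8a had 2, 5 and 7 counts at 0 h in fibroblasts. At 2 h it belonged to Tlr7 (3.89, SE 0.655), Phex (4.70), L3mbtl2 (1.00), Cmpk2 (4.88), Slc49a4 (-1.14, SE 0.214), Sema6b (-2.74), Smap2 (-0.96) and Dll1. They were at an edgeR adjusted p of 0.0563 to 0.15, and several were near 0 in the libraries labelled aortic endothelial. There Dll1 had 0 counts at 0 h and 27, 7 and 15 at 2 h, Phex had 3, 0 and 0 counts at 0 h, Sema6b had 4, 0 and 3 counts at 2 h, and Cmpk2 was at 0.191, 0 and 0.0759 CPM at 0 h. Without the first 0 h library so labelled the counts at 1 and 2 h were 132 and 132, and without the first 1 h library 37 and 13. They were 6 and 14 without the third 2 h library and 5 and 5 without the third 0 h library. The 1 h count was 3 without the second 1 h library so labelled. It was 1 without the third 1 h or the first 2 h library so labelled, or the second 1 h or the third 0 h fibroblast library. The 2 h count was 8 without the first or second 2 h library, 5 without the third 1 h and 2 without the second 0 h library so labelled. It was 1 without the first 0 h or the third 2 h fibroblast library.

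Genes tied to ImP by earlier knowledge did not pass as labelled. Nisch, which encodes the imidazoline receptor candidate nischarin, was at 327 ± 15 CPM in macrophages, 307 ± 15 CPM in fibroblasts and 96.6 ± 9.9 CPM in the libraries labelled aortic endothelial at 0 h. Its log2 fold changes at 1 and 2 h were 0.10 and 0.08 in macrophages (edgeR adjusted p = 0.954 and 0.859). They were -0.08 and 0.01 in fibroblasts (edgeR adjusted p = 0.886 and 1), and 0.23 and 0.35 in the libraries labelled aortic endothelial (edgeR adjusted p = 0.826 and 0.539). The fibroblast values were 0.01 at 1 h with the gene-length trend removed and -0.02 at 2 h with library totals, so their direction is not settled, and Nisch overlaps Tnnc1 on the opposite strand. The mTOR pathway components, a pathway through which ImP is known to act in liver, had medians between -0.01 and 0.11 over the 9 comparisons. The lowest camera adjusted p was 0.126, in the libraries labelled aortic endothelial at 2 h (adjusted p = 0.694 with an estimated correlation). With the third library of each ImP group left out, 27 mTOR components had a median of 0.065 in macrophages at 2 h with 0 members past the threshold in edgeR (camera adjusted p = 0.0458, adjusted p = 0.394 with an estimated correlation). These comparisons measure transcripts and not phosphorylation of mTOR targets.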

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

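The tests of exchanged labels and of a delayed response in macrophages, and those on the markers of the libraries labelled aortic endothelial, were chosen after the result was seen. The tests of depth and quality, of gene length and of a single library had predictions set before, but they address patterns seen in these data. The fit with the gene-length trend removed was itself chosen after the values were seen. The counts of other splits were set before.

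A test of the difference between cell types singled out the following results among others. Between macrophages and fibroblasts they were Id3 at 1 h (2.64, SE 0.304, edgeR adjusted p = 0.000115) and at 2 h (2.58, SE 0.304, edgeR adjusted p = 0.000177) and Smad6 at 2 h (3.53, SE 0.602, edgeR adjusted p = 0.0351). Between the libraries labelled aortic endothelial and macrophages they included at 1 h Id3 (-3.04, edgeR adjusted p = 7.79e-06) and Tbkbp1 (-1.84, edgeR adjusted p = 0.0423), and at 2 h Id3 (-2.83, edgeR adjusted p = 3.07e-05), Smad6 (-3.31), Slc49a4 (-1.31) and Tlr7 (3.35). The low-input kit was used for all libraries labelled aortic endothelial and for none of the others, so for differences with those libraries the kit and the cell type cannot be told apart. Sex is tied to the label as well: the X-inactivation transcript Xist was at 764 CPM or more in the macrophage libraries, at 256 CPM or more in the fibroblast libraries and at 0.721 CPM or less in those labelled aortic endothelial. Tlr7 lies on the X chromosome.

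In macrophages, the third library labelled 1 h lacked and the third library labelled 2 h showed the inflammatory and immediate early genes that separate the other 1 h libraries from the other 2 h libraries, with Tnf at 18.2 CPM in the first and 267 CPM in the second. Low depth or RNA quality is argued against, since at most 1 of 3 measures (total counts, genes detected, mitochondrial share) lay outside the range of the other 7 libraries in either. A delay of the third set of cultures would leave genes that are higher at 2 h at their early level in the library labelled 1 h, and that library lay at a median position of 1.129 on the way from the other 1 h libraries (0) to the other 2 h libraries (1) over 7 such genes, which argues against it. An exchange of the labels of these libraries remains as a candidate explanation: over 89 genes called between 1 and 2 h without them, the library labelled 2 h lay at a median position of 1.034 and the library labelled 1 h at -0.051, on a scale with the other 2 h libraries at 0 and the other 1 h libraries at 1. The library numbers in the labels are out of order in this set, with 23 at 1 h and 22 at 2 h, while in the other 8 sets the 1 h number comes first, and no biological explanation other than the delay was tested. Not every gene followed an exchange. Ptger1 was at 5.16 CPM in the library labelled 1 h, against 4.69 and 5.33 CPM in the other 1 h libraries. It was at 9.89 CPM in the library labelled 2 h.

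In fibroblasts, the cytosolic ribosomal protein genes were lower at 2 h than at 1 h over the list alone (62 of 77, median -0.245), with 0 past the threshold over all genes in edgeR and the camera call lost (adjusted p = 0.703 with an estimated correlation). A single library as the whole source is argued against, since the median stayed at -0.166 or lower whichever of the 6 libraries was left out. With each library's trend on gene length removed the median was -0.113, and -0.078 when the third 1 h library was also left out, so a trend of recovery with gene length and a change of these short genes with time cannot be told apart here: removing the trend took away part of the difference, and what was left moved with 1 library.

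The libraries labelled aortic endothelial lacked most endothelial transcripts. Low sensitivity of the low-input kit is argued against, since these libraries had a median of 14235 genes with at least 10 counts, against 12998 in macrophages and 13699 in fibroblasts. An exchange with the fibroblast libraries is argued against, since those carried 1 of 14 endothelial markers above 10 CPM (Flt1). Mesenchymal cells in these cultures are a candidate explanation: 14 of 19 fibroblast and smooth muscle markers lay above 10 CPM, with Acta2 at 798 CPM and Col1a1 at 544 CPM. Whether these cells were endothelial before culture was not tested.

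For each comparison of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. In macrophages 1 split of 10, the real one, gave as many genes at 1 h (3 genes, highest other 2) and at 2 h (4, highest other 3). For 2 h against 1 h the real split gave 0 genes, so all 10 gave as many, and the highest other, 178 genes, put the first and second 1 h libraries with the third 2 h library, which points to a structure of the samples. It is the grouping that an exchange of the labels of the third 1 h and 2 h libraries would give. This count rests on the same values that raised that question. In fibroblasts all 10 splits gave as many as the real 0, with highest others of 40 at 1 h, 1 at 2 h and 2 between 1 and 2 h, and the 40 also points to a structure of the samples. In the libraries labelled aortic endothelial all 10 gave as many as the real 0, with highest others of 0, 0 and 1. Over any time, 12 of 100 splits gave at least the 3 genes of macrophages (highest other 130). The split with 130 genes again put the first and second 1 h libraries with the third 2 h library, a structure of the samples. The share therefore does not measure chance alone, and chance was not excluded. For the 0 genes of fibroblasts (highest other 4) and of the libraries labelled aortic endothelial (highest other 1), 100 of 100 splits gave as many by construction, which decides nothing. For differences between cell types, 1 of 30 splits, the real one, gave as many genes for macrophages against fibroblasts at 2 h (2 genes, highest other 1), a share under 0.05. That is the smallest share that 30 splits can give, and it was not adjusted for the other comparisons, so it does not exclude chance. The margin was 1 gene, and the count was 1 with limma-voom and from 1 to 2 with 1 library left out. Id3 and Smad6 were lost when only these cell types entered the fit. Chance was not excluded at 1 h (10 of 30, 1 gene, highest other 2) or for the libraries labelled aortic endothelial against macrophages at 1 h (19 of 30, 2 genes, highest other 71) and 2 h (2 of 30, 9 genes, highest other 9). Against fibroblasts the real counts were 0 at 1 h (30 of 30, highest other 66) and at 2 h (30 of 30, highest other 11), so these splits decide nothing. The splits with 71, 66 and 11 genes point to a structure of the samples.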

How the results depend on the processing

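The fits without the third library of each macrophage ImP group and those with the gene-length trend removed were chosen after the result was seen. The other alternatives were set before. Over the named genes and their alternatives 2120 values kept direction and side of the threshold, 88 lost and 163 gained a call, and 6 turned direction, all for Nisch in fibroblasts: at 1 h 0.01 with the length trend removed, and at 2 h -0.02 with library totals, -0.043 with the length trend removed, -0.043 with the first 1 h library left out as well, -0.032 without the second 0 h and -0.035 without the third 2 h library. Without the first 2 h library it was 0.031 (the cause was not tested).

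Counts that moved by over 1.5 times are given in order of 1 h, 2 h, 2 h against 1 h and any time; the cause was not tested except where fewer genes or libraries enter by construction. With DESeq2 they were 13, 15, 1 and 16 in macrophages, 10, 5, 308 and 126 in fibroblasts, and 1, 22, 6 and 17 in the libraries labelled aortic endothelial. Limma-voom gave 5, 1 and 5 in macrophages at 1 h, between 1 and 2 h and at any time. Without a low-count filter they were 9, 10, 1 and 12 in macrophages, 1, 1, 38 and 19 in fibroblasts, and 6, 1 and 5 in the libraries labelled aortic endothelial from 2 h on. With only the compared groups macrophages had 5 and 2, with an absolute log2 fold change of at least 1 they had 0 and 0, and without the third library of each ImP group 125, 16, 89 and 130. Fibroblasts between 1 and 2 h had 1 with the length trend removed and the first 1 h library left out.

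For differences between cell types at 1 and 2 h, DESeq2 gave 5 and 4 (macrophages against fibroblasts), 47 and 106 (libraries labelled aortic endothelial against macrophages) and 81 and 63 (against fibroblasts). Macrophages against fibroblasts gave 1 at 2 h with limma-voom, 0 and 0 with these cell types alone, and 27 at 1 h without the third library of each ImP group. Against macrophages, the libraries labelled aortic endothelial gave 1 and 1 with limma-voom, 1 at 1 h with library totals, 38 at 1 h without the third library of each ImP group, and 4 and 14 with the length trend removed. Against fibroblasts they gave at 2 h 2 with RLE (1 higher), 9 with library totals (8 higher), 4 without a filter and 2 at a mean of 1 CPM. The cause was not tested.

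With 1 library left out, counts ran from 2 to 7, 1 to 6 and 2 to 4 in macrophages (1 h, 2 h, any time), from 0 to 1, 0 to 365 and 0 to 30 in fibroblasts (1 h, 2 h against 1 h, any time), and from 0 to 1 at 1 h and at 2 h in the libraries labelled aortic endothelial. Differences ran from 1 to 3 and 1 to 2 (macrophages against fibroblasts), 1 to 62 and 1 to 148 (libraries labelled aortic endothelial against macrophages) and 0 to 132 and 0 to 132 (against fibroblasts). Gene lists past the threshold at 1 h, 2 h and 2 h against 1 h numbered 14, 10 and 4 in macrophages (9 to 15, 7 to 14 and 0 to 8 with 1 library left out), 21, 11 and 11 in fibroblasts (11 to 23, 9 to 16, 4 to 18) and 6, 6 and 3 in the libraries labelled aortic endothelial (2 to 7, 5 to 8, 1 to 6). With an estimated correlation they were 1, 1 and 0 in macrophages and 0 in the others, with fry 2, 3 and 0 in macrophages and 0 in the others, and 7 in macrophages between 1 and 2 h without the third library of each ImP group; the cause was not tested.

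Runs of library codes as a block were not taken as pairing, since the labels do not say what a run is. Libraries of 1 run had correlated deviations over 0.1 in 1 of 9 pairs in macrophages and 5 of 9 in fibroblasts. In the libraries labelled aortic endothelial 4 of 9 did. Correlations within runs reached 0.2, 0.47 and 0.26 in that order, and between runs 0.32, 0.28 and 0.14. A shared effect of runs is therefore not excluded in fibroblasts and in the libraries labelled aortic endothelial. With the block, edgeR genes at an unadjusted p under 0.05 at 1 h went from 826 to 1158 and from 733 to 1127 there. With this block the counts were 2 in macrophages at 1 h (Id2 and Skil, without Bhlhe40), 1 and 1 in fibroblasts at 1 h and at any time, 1 for macrophages against fibroblasts at 2 h, 10 and 15 for the libraries labelled aortic endothelial against macrophages and 3 and 8 against fibroblasts. Small changes were hardest to find in the libraries labelled aortic endothelial, with totals from 19 to 61 M counts and a biological coefficient of variation of 0.326 against 0.126, and depth was not separated from this spread. Named genes of few counts that a filter removed, such as Olfr373, Cd247 and Tcte3, have no value under that setting, and the test over any time has none for the fold threshold or for the compared groups alone. Other gene annotations, other aligners and counting by strand were not run.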

Other observations

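The fit without the third library of each macrophage ImP group and the tests in it were chosen after the result was seen.

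In that fit, 3 of 10 glucocorticoid targets rose in macrophages at 1 h, the phosphatase Dusp1 (1.91, SE 0.101, edgeR adjusted p = 1.76e-07), the EGF receptor inhibitor Errfi1 (2.11, SE 0.151) and the kinase Sgk1 (0.82, SE 0.07), and the list held with an estimated correlation (adjusted p = 0.00669). Dusp1 is also in the immediate early list, and the glucocorticoid list was not tested without it. Of 18 p53 targets 2 rose, the stress cytokine Gdf15 (1.49, SE 0.074, edgeR adjusted p = 2.99e-08) and the antiproliferative gene Btg2 (1.57, SE 0.085), which is also in the immediate early list (adjusted p = 0.0328 with an estimated correlation).

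In fibroblasts, genes of the interferon response had a median of -0.66 between 1 and 2 h, with 0 of 24 members past the threshold in edgeR and Isg15 at -0.53 (SE 0.147, edgeR adjusted p = 0.2) (camera adjusted p = 6.52e-06, adjusted p = 0.703 with an estimated correlation). The first 1 h library stood apart, with the list member Ifit1 at 22.3 CPM against 11.4 and 9.75 CPM in the other 1 h libraries. In macrophages, 1 unstimulated library held 1.98% of its counts in the transcript CT010467.1.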
